A study of Mus musculus with 3 samples.

How the data were processed

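Total RNA-seq of the chromatin fraction was analysed in 3 libraries of mouse bone-marrow-derived macrophages, all of 1 group, which the labels call biological replicates 1 to 3. Per the labels, the cells were exposed to Lipid A at 100 ng per ml for 12 h, washed out for 12 h and taken at minute 0 of a second exposure. Fragment sizes of 250 to 400 are given there too.

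Each library has a gene table, an alignment-based transcript table and a read-based transcript table. Per the README files deposited with each library, the gene and alignment-based tables were made from a transcriptome alignment on mm10 with the GENCODE M21 annotation, and the read-based table from the reads and an index. The aligner, the versions and the strand setting are not given in the sources used here. Expected counts, estimated reads that need not be whole, were deposited by the authors without normalization. TPM values were deposited by the authors over all rows of a table, including tRNA and phiX rows, so they sum to 1000000 per library and short RNAs take much of that sum. For long transcripts the effective length in the deposited tables is the length less a fixed amount per library. A row near an effective length of 0 can therefore have a very large TPM or a TPM of 0. All 55536 gene IDs matched GENCODE M21, and 86 of them have no row in the read-based table. Gene names, types and coordinates are from that annotation.

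Depth was 11958978, 17283529 and 19475027 expected counts in replicates 1, 2 and 3, and 18600052, 31838203 and 33200218 estimated counts in the read-based tables. Rows that name no gene held 1.31%, 0.48% and 0.24% of the expected counts and stayed out of library sizes and tests. A count of 3 in a library, the most that a count of 0 allows, equals 0.254, 0.174 and 0.154 CPM in replicates 1, 2 and 3. Intervals for shares are 95% Wilson intervals; these and the floors cover counting error only, since reads without molecular identifiers are not independent molecules.

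Levels are TPM from the gene table. IDs sharing a symbol within a class were summed. The median log2(TPM + 1) over each of 17 gene lists and 10 cell type lists was compared with 10000 random lists of the same size from all annotated protein-coding genes, or from non-coding genes for the 2 RNA lists, with a two-sided p and Benjamini-Hochberg adjustment over the 27 lists. A call also needed the same side of the background in all 3 libraries. The smallest p these permutations can give is 0.0002. Differences between lists used 100000 permutations of genes, or all of them where that was feasible, adjusted over 14 contrasts. These p-values describe lists in these libraries: genes are not independent replicates, and a sign-flip test over 3 libraries cannot go below 0.25.

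Replicate variability was fitted with edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers, with filterByExpr, TMM scaling and an intercept only. Each gene's quasi-dispersion was tested against the fitted trend. Ratios between 2 libraries are of TMM-normalized CPM with 0.1 added, over members with a mean of at least 10 counts, and were set against 10000 random lists drawn within 50 ranks of mean expression. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The libraries were checked for duplicates; counts of each pair differed far beyond sampling noise (chi-square per degree of freedom from 39.1 to 72.0).

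The steps were tested on simulated data. Over-dispersion was recovered in 40% of genes changed 2-fold and 100% of genes changed 4-fold, 8-fold or 16-fold in 1 of 3 simulated libraries, with 6 false calls among 15364 unchanged genes. A coefficient of 0.15 was recovered as 0.149 without the changed genes and as 0.208 with the 200 changed genes present. In the permutation tests, random lists of 20 genes passed a threshold of 0.05 in 4.5% of cases against the background and 3% between lists; lists shifted by 2 log2 units passed in 42.5% and 69%. For retained-intron shares the corresponding values were 8% with no shift and 97% with a shift of 25 percentage points.

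The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Named are 15 fixed genes, the 3 highest members and the lowest member of each list, and the 10 highest protein-coding and non-coding genes. Also named are the 10 protein-coding genes of at least 5 TPM with the largest SD, the 10 smallest p among over-dispersed genes, the 5 largest differences between the quantifications in each direction, and the 5 highest retained-intron shares. Where members tie at 0 as the lowest, the last in list order is named. Some genes that this rule picks are left out of the text. Clec7a, Mx2, Cxcl11 and Trac have another gene type in the annotation and Ahsp has no gene of that name, so these were left out of their lists. Alternatives were the read-based quantification, TPM renormalized over nuclear protein-coding and long non-coding genes, a pseudocount of 0.1, a filter at a mean of 0.5 TPM, TMM-normalized CPM, relative log expression scaling, other count filters and leaving out each library.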

Results

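RNA bound to chromatin was measured in mouse bone-marrow-derived macrophages, which are primary cells grown from bone marrow of the C57BL/6J strain. The cells had been exposed to Lipid A, the part of bacterial lipopolysaccharide that activates the receptor TLR4, at 100 ng per ml for 12 h. Lipid A was then washed out for 12 h, and the cells were collected at minute 0 of a second exposure. The fraction holds nascent and nuclear-retained transcripts, and ribosomal RNA was depleted before sequencing. The labels give 1 group of 3 biological replicates and no untreated control, so each value is a level in this state and not a response to Lipid A. All 3 carry 1 donor identifier, and the labels do not say whether the cultures came from separate animals. Starting RNA was 1000 ng in replicate 1, 250 ng in replicate 2 and 500 ng in replicate 3. Expected counts summed to 11958978, 17283529 and 19475027 in replicates 1, 2 and 3. At a mean of at least 1 TPM (transcript abundance scaled to a fixed sum per library), 15365 genes were detected, of which 10877 were protein-coding and 1766 long non-coding; the read-based quantification gave 23429 genes, 4095 of them long non-coding. Values written with ± are the mean and SD of the 3 libraries.

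The question for the inflammatory genes was which of them were present on chromatin in this state. Transcripts of Ccl5, a chemokine, were the highest of the 24 cytokine, chemokine and mediator genes at 188 ± 24.99 TPM (SD, n = 3). Tnf, encoding tumor necrosis factor (chromosome 17, 35199381 to 35202007, mm10), stood at 50.01 ± 9.87 TPM and the chemokine gene Ccl4 at 49.0 ± 12.6 TPM. Of the 24 genes, 8 were at 10 TPM or more on average. Il1b was at 5.21 ± 0.73 TPM, Il6 at 0.54 ± 0.35 TPM and Il12b at 0.18 ± 0.28 TPM. Csf2 had no reads in the alignment-based table and a read-based mean of 0.18 TPM. In all, 13 of the 24 genes reached 1 TPM in every library and 9 stayed under 1 TPM in every library. Nos2, encoding inducible nitric oxide synthase, was at 3.87 ± 0.84 TPM. The list's median log2(TPM + 1) was 2.43, at percentile 90.6 of 10000 random lists of protein-coding genes (adjusted p = 0.32, two-sided permutation test over genes).

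Negative regulators of TLR and NF-kB signalling were present almost throughout, with 24 of 25 genes at 1 TPM or more in every library. The highest were Inpp5d, a lipid phosphatase, at 200 ± 51.2 TPM, Ptpn6, a tyrosine phosphatase, at 118 ± 7.92 TPM, and Tnip3 at 118 ± 13.2 TPM. Nfkbia, encoding the NF-kB inhibitor IkB-alpha, was at 53.3 ± 11.1 TPM and Tnfaip3, encoding the ubiquitin-editing enzyme A20, at 51.9 ± 2.05 TPM. Irak3, a kinase-like inhibitor of TLR signalling, stood at 23.5 ± 1.29 TPM, Il10 at 9.91 ± 6.24 TPM and Socs3 at 5.71 ± 0.49 TPM. Sigirr was the lowest member at 0.70 ± 0.30 TPM. The median log2(TPM + 1) of 4.61 lay above all random lists (adjusted p = 0.00049, from the smallest p that 10000 random lists can give).

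**Figure D1:**
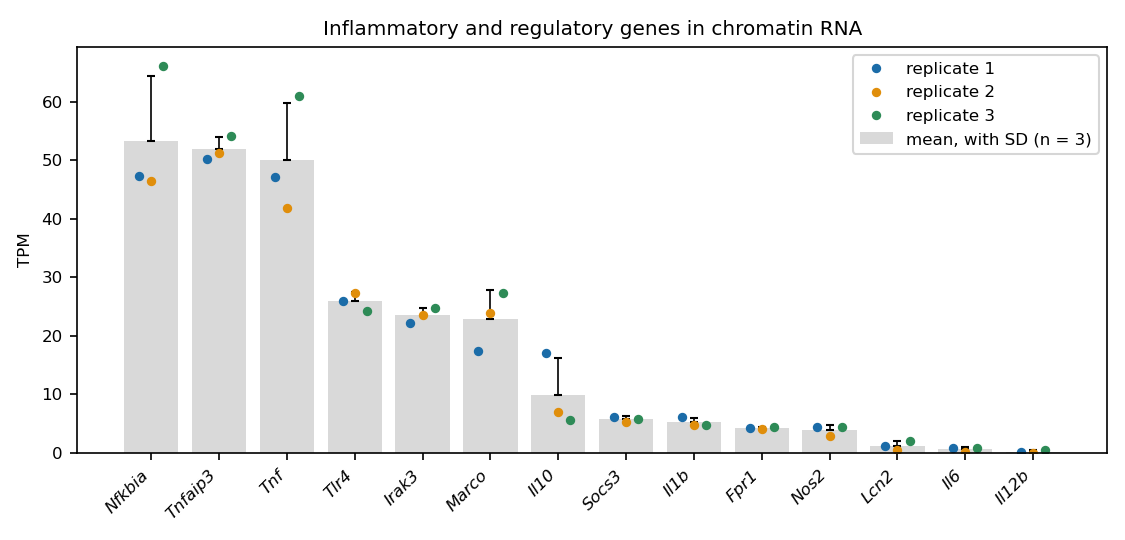
TPM (vertical axis) of 14 genes fixed before the data were examined, in 3 libraries of chromatin RNA. Bars are means with the SD drawn upward, and points are the libraries; Nfkbia, Tnfaip3 and Tnf lay near 50 TPM, and Il6 and Il12b lay under 1 TPM.

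Set against the cytokine list, the negative regulators were higher by 2.18 in median log2(TPM + 1), and by 2.13, 2.72 and 2.08 in replicates 1, 2 and 3 (adjusted p = 0.0045, two-sided permutation test of genes between the lists). Interferon-stimulated genes were higher than the cytokine list by 4.66 (SD 0.28 over 3 libraries, adjusted p = 0.00042). Antimicrobial genes differed from it by 2.26 (adjusted p = 0.19), immediate-early genes by -0.55 (adjusted p = 0.63) and alternative-activation genes by -2.03 (adjusted p = 0.19), and none of these 3 passed the threshold. With genes under a mean of 0.5 TPM left out, the difference between regulators and cytokines was 1.07 and no longer passed (adjusted p = 0.23). In TMM-normalized CPM the antimicrobial list did pass (difference 2.81, adjusted p = 0.034).

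Interferon-stimulated genes were the highest of the protein-coding lists fixed beforehand, with 25 of 26 members at 10 TPM or more on average and 16 at 100 TPM or more. Mx1, an interferon-induced GTPase gene, was the highest protein-coding gene of the data at 2023 ± 627 TPM (chromosome 16, 97447035 to 97462907). Stat2, encoding a transcription factor of the interferon response, followed at 723 ± 108 TPM. Cxcl9 was the lowest at 0.02 ± 0.02 TPM, with a read-based mean of 1.40 TPM. The list's median log2(TPM + 1) was 7.09 (adjusted p = 0.00049).

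Antimicrobial, acute-phase and pattern-recognition genes also lay above the random lists, with a median log2(TPM + 1) of 4.69 (adjusted p = 0.00049). The lysozyme gene Lyz2 was at 177 ± 67.5 TPM, Acod1, which makes itaconate, at 166 ± 39.6 TPM, and the metal transporter gene Slc11a1 at 163 ± 47.3 TPM. Marco, a scavenger receptor, stood at 22.9 ± 5.04 TPM, Fpr1, a formyl peptide receptor, at 4.19 ± 0.19 TPM and Lcn2 at 1.18 ± 0.75 TPM. Slpi had no reads in either quantification. Of 20 measured members, 14 were at 1 TPM or more in every library and 4 were under 1 TPM in every library.

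All 21 TLR4 signalling components were at 1 TPM or more in every library, with a median log2(TPM + 1) of 4.52 (adjusted p = 0.00049). Tlr4 itself (chromosome 4, 66827584 to 66930284) was at 25.9 ± 1.53 TPM. The kinase genes Tbk1 and Chuk were at 181 ± 17.6 and 103 ± 3.18 TPM, the transcription factor gene Irf3 at 97.52 ± 13.7 TPM, and the adaptor gene Tirap, the lowest, at 4.47 ± 0.65 TPM. With genes under a mean of 0.5 TPM left out of list and background, the list missed the threshold (adjusted p = 0.061).

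Lists of immediate-early, alternative-activation, oxidative-stress, histone and proliferation genes were not separated from random lists. Among 18 immediate-early genes Klf6 was at 85.0 ± 4.51 TPM, Junb at 28.2 ± 2.19 TPM, Jun at 18.5 ± 1.38 TPM and Fosb at 0.15 ± 0.10 TPM (list median 1.88, adjusted p = 0.54). Among 13 alternative-activation genes Il4ra was at 73.4 ± 27.4 TPM, Mrc1 at 41.9 ± 10.8 TPM and Clec10a at 6.14 ± 2.14 TPM, while Ccl24 had no reads alignment-based and a read-based mean of 7.08 TPM (list median 0.40, adjusted p = 0.73). Prdx1, Sqstm1 and Sod2 were at 155 ± 27.7, 140 ± 34.7 and 119 ± 10.6 TPM, and Nqo1 at 0.28 ± 0.18 TPM (oxidative-stress list median 2.80, adjusted p = 0.32). Replicate 3 raises the level of this list, with medians of 4.23, 5.365 and 14.65 TPM in replicates 1, 2 and 3. Hist1h4i, Hist1h1c and Hist1h2bg were at 10 ± 2.40, 7.70 ± 1.77 and 7.48 ± 1.33 TPM, and Hist1h3b at 0.24 ± 0.22 TPM (histone list median 2.14, adjusted p = 0.54). Of the proliferation genes Pcna was at 24.7 ± 2.62 TPM, Mcm6 at 9.46 ± 2.02 TPM, Mcm2 at 6.19 ± 2.55 TPM and Ccnb2 at 0.64 ± 0.63 TPM (list median 2.05, adjusted p = 0.46). With genes under a mean of 0.5 TPM left out, the immediate-early list (adjusted p = 0.041) and the proliferation list (adjusted p = 0.026) lay below the background.

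Lysosome, glycolysis and sterol genes were well represented. All 18 lysosome genes and all 18 glycolysis genes were at 1 TPM or more in every library. Gpnmb was at 959 ± 101 TPM, Psap at 677 ± 61.0 TPM and the protease gene Ctsb at 440 ± 44.1 TPM. The hexokinase gene Hk3 was at 327 ± 39.8 TPM, Pkm at 130 ± 30.8 TPM, Pfkfb3 at 76.8 ± 17.3 TPM and the glucose transporter gene Slc2a1 at 1.41 ± 0.33 TPM. The lipid transporter genes Abca1 and Abcg1 were at 111 ± 27.6 and 94.3 ± 18.1 TPM, Apoe at 100 ± 62.2 TPM and Sqle at 8.10 ± 1.45 TPM. Median log2(TPM + 1) was 6.55 for lysosome, 4.78 for glycolysis and 5.39 for sterol and LXR genes (adjusted p = 0.00049 for each).

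Among nuclear RNAs, Malat1 stood at 23280 ± 8269 TPM, Neat1 at 1922 ± 295 TPM and Xist, the RNA that coats the inactive X chromosome, at 983 ± 44.0 TPM (chromosome X, 103460366 to 103483254). Tsix, antisense to Xist, was at 0.09 ± 0.02 TPM; the strand setting of the counting is not given in the sources used here, so overlapping antisense genes are uncertain. The small RNAs Rmrp, Rn7sk and Rn7s1 were at 81471 ± 37552, 18885 ± 4891 and 7414 ± 2699 TPM, and Rnu11 had no reads in either quantification. Both lists lay above random lists of non-coding genes (median log2(TPM + 1) 4.77 and 9.83, adjusted p = 0.00049). Cytoplasmic ribosomal protein genes had a median of 5.20 (adjusted p = 0.00049), with Rps9 at 131 ± 46.6 TPM, Rpl3 at 113 ± 32.4 TPM, Rps24 at 112 ± 46.7 TPM and Rps23 at 20.4 ± 15.4 TPM; processed pseudogenes of these genes can share their reads. Replicate 3 raises these levels, with list medians of 22.2, 26.1 and 80.2 TPM in replicates 1, 2 and 3. Mitochondrial mRNAs had a median of 5.06 (adjusted p = 0.0013), with mt-Atp8 at 310 ± 278 TPM, mt-Co1 at 272 ± 89.8 TPM, mt-Nd6 at 78.7 ± 61.9 TPM and no alignment-based reads of mt-Co2, whose read-based mean was 35.4 TPM. Replicate 3 was also the highest for the mitochondrial list, with medians of 32.9, 15.6 and 82.01 TPM in replicates 1, 2 and 3. In TMM-normalized CPM the mitochondrial list missed the threshold (adjusted p = 0.19).

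**Figure D2:**
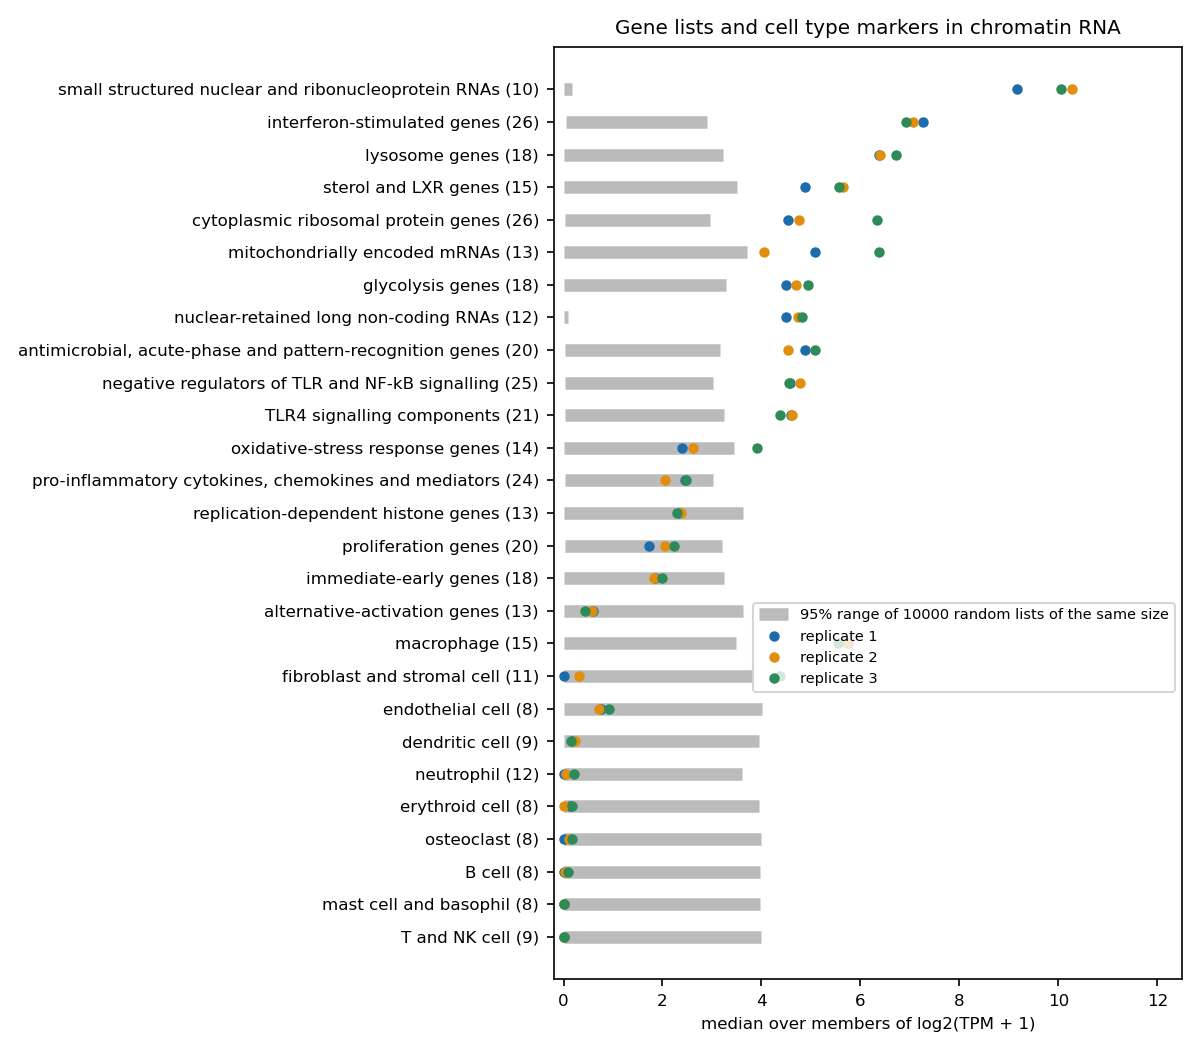
Median log2(TPM + 1) over the members of each list (horizontal axis) in each library, with the number of measured members in brackets. Grey bars span 95% of 10000 random lists of the same size, and the interferon-stimulated list lay at 7.09 on average, above its grey bar in all 3 libraries.

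The next question was which cell types the libraries held. Macrophage markers were high, with 14 of 15 at 1 TPM or more in every library and a median log2(TPM + 1) of 5.68 (adjusted p = 0.00049). Adgre1, encoding the F4/80 antigen, was at 347 ± 77.2 TPM, Csf1r, the receptor for macrophage colony-stimulating factor, at 127 ± 1.30 TPM, Mertk at 120 ± 15.5 TPM and Cx3cr1 at 0.59 ± 0.93 TPM, from 1, 4 and 101 counts in replicates 1, 2 and 3. The macrophage list exceeded each of the 9 other cell type lists in all 3 libraries. On levels averaged over the libraries, the differences in median log2(TPM + 1) were 4.12 to 5.66 (adjusted p from 0.0012 to 0.0045, exact permutation test or permutation test of genes between lists). The smallest difference in a single library was 1.19, from the stromal list in replicate 3. With genes under a mean of 0.5 TPM left out, the difference from the osteoclast list missed the threshold (adjusted p = 0.066).

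None of the other cell type lists was separated from random lists. Only 49.4% of annotated protein-coding genes reached a mean of 1 TPM, so a short list without expression is hard to call lower. The missing calls therefore do not show presence or absence of a cell type. Some members were present: 4 of 8 endothelial and 3 of 9 dendritic markers were at 1 TPM or more in every library. Csf3r, the receptor for granulocyte colony-stimulating factor, was at 86.8 ± 18.6 TPM, whereas Ngp and Mmp8 were at 0.25 ± 0.10 and 0.24 ± 0.07 TPM and Mpo had no reads. Vwf, Kdr and Egfl7 of the endothelial list were at 26.8 ± 5.17, 6.06 ± 3.46 and 2.86 ± 1.51 TPM, and Tie1 had no reads. Alas2 was at 15.4 ± 5.20 TPM, Epor at 0.61 ± 0.65 TPM and Hba-a2 at 0.15 ± 0.13 TPM. Batf3, Zbtb46 and Itgae of the dendritic list were at 5.59 ± 2.18, 1.57 ± 0.08 and 1.06 ± 0.04 TPM, with no reads of Cd209a. Atp6v0d2, Ctsk and Acp5 of the osteoclast list were at 2.23 ± 0.46, 1.503 ± 1.22 and 0.72 ± 0.13 TPM, with no reads of Ocstamp. Cd5, Lck and Cd8a were at 1.75 ± 0.44, 0.26 ± 0.42 and 0.11 ± 0.06 TPM, and Zap70 at 0. Ebf1, Cd79a and Cd79b were at 0.30 ± 0.53, 0.10 ± 0.03 and 0.09 ± 0.08 TPM, and Vpreb3 at 0; the reads of Ebf1 were all in replicate 3 (68 counts). Kit, Gata2 and Mcpt8 were at 0.79 ± 0.55, 0.11 ± 0.19 and 0.03 ± 0.06 TPM, and Cma1 at 0. These values of 0 are alignment-based; read-based means were 4.19 TPM for Ocstamp, 1.95 TPM for Mpo, 1.26 TPM for Tie1, 0.02 TPM for Zap70 and for Vpreb3, and 0 for Cd209a and Cma1.

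Fibroblast and stromal markers were different between libraries. Col1a1, encoding a chain of type I collagen (chromosome 11, from 94936224), was at 0.01, 0.43 and 149 TPM in replicates 1, 2 and 3, from 1, 34 and 14624 expected counts. Col1a2 was at 0.03, 0.31 and 116 TPM and Col3a1 at 0, 0.43 and 102 TPM, while Pdgfra had reads in replicate 3 alone, at 2.22 TPM. Of the 11 markers, 10 were at least 10 times as high in replicate 3 as in each other library, with fewer than 3 counts elsewhere set to 3; Fbn1 was the exception. The macrophage list exceeded the stromal list by 5.74 and 5.42 in replicates 1 and 2 and by 1.19 in replicate 3.

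**Figure D3:**
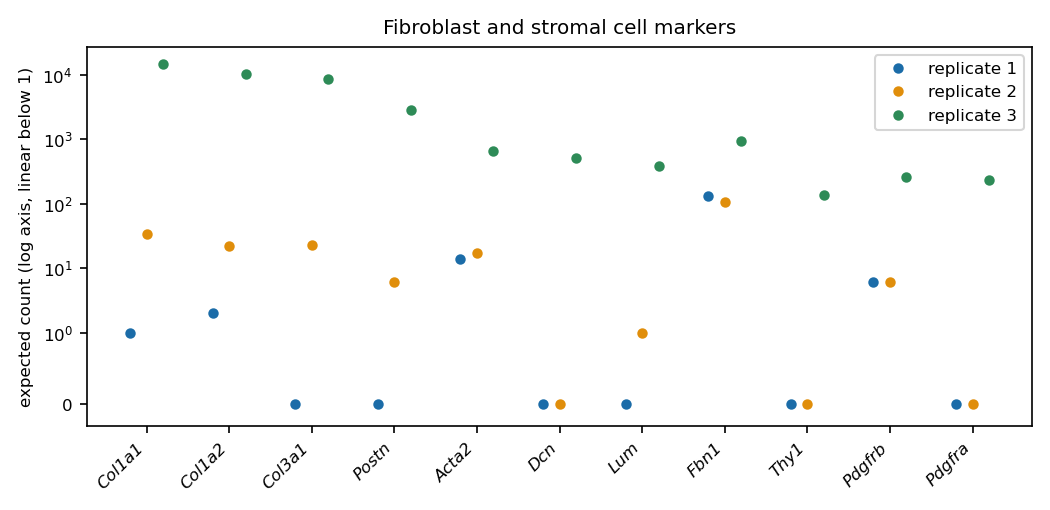
Expected counts (vertical axis, logarithmic above 1 and linear below) of the 11 fibroblast and stromal markers in each library. Replicate 3 was the highest for all 11 genes, reaching 14624 for Col1a1 against 1 and 34 in replicates 1 and 2.

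The libraries were next compared with each other. Across 14839 genes, Pearson correlations of log2(CPM + 1) were 0.984 for replicates 1 and 2, 0.977 for 1 and 3 and 0.980 for 2 and 3, and Spearman correlations were 0.981, 0.972 and 0.976; these are across genes, which are not independent replicates. The common biological coefficient of variation was 0.212. In simulated libraries, 200 changed genes raised this estimate from 0.149 to 0.208, so genes that differ between libraries can raise it. Those genes were drawn from genes with a mean of at least 50 reads. In the data the filter removed genes such as Col1a1, so the simulation cannot account for the 0.212. The correlations leave out the same filtered genes. The protein-coding genes of at least 5 TPM with the largest spread were Col1a1, Sparc, Col1a2, Col3a1, Igf2, Bgn, Ptn, mt-Nd4l, Serpinh1 and Postn, with an SD of log2(TPM + 1) from 3.30 to 4.03. All 10 were highest in replicate 3; Sparc, for example, was at 0, 0.27 and 126 TPM, and Igf2, an imprinted growth factor gene, at 0, 0.56 and 99.2 TPM.

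In edgeR's quasi-likelihood fit, 24 genes were more variable than the trend (Benjamini-Hochberg adjusted p under the threshold of 0.05), and 862 had an unadjusted p under 0.05. Of these, 16 were protein-coding and high in replicate 3. Lox, a collagen cross-linking enzyme gene, was at 3.596, 1.60 and 156 CPM (adjusted p = 0.017), and Acta2, Ogn, Col4a2, Rplp0, Rplp1, Igfbp4, Mgp, Ckap4 and Loxl2 had the next smallest p (adjusted p = 0.049 each). The other 8 were small nuclear RNA genes high in replicate 1, Rnu1a1 at 90.8, 11.9 and 18.7 CPM among them; 7 of these hold identical values and cannot be separated by reads. Without replicate 1, 2 or 3 the test called 38, 0 and 78 genes, and 727 had an unadjusted p under 0.05 without replicate 2. The filter asks for a minimum count in all 3 libraries and so removed genes such as Col1a1, and with no filter 677 genes were called. At a mean of at least 50 reads 180 genes were called, and among nuclear protein-coding genes alone only 1, so most of the protein-coding calls depend on the genes tested with them.

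Interferon-stimulated genes were higher in replicate 1 than in replicate 2 by a median log2 ratio of 0.51 and than in replicate 3 by 0.61, with all 25 members tested higher in both pairs. Cytokine genes were higher in replicate 1 than in replicate 2 by 0.80 (16 of 17 genes) and than in replicate 3 by 0.31 (12 of 17). Negative regulators were higher in replicate 1 by 0.25 over replicate 2 (20 of 25 genes) and by 0.12 over replicate 3 (17 of 25). For antimicrobial genes the ratios were 0.51 over replicate 2 (12 of 16 genes higher) and 0.05 over replicate 3 (9 of 16). The ratio of replicate 2 over 3 was -0.57 for cytokine genes, and 3 of 17 were higher in replicate 2. Ribosomal protein genes were higher in replicate 3, with ratios of -1.58 against replicate 1 and -1.67 against replicate 2. Mitochondrial mRNAs gave 1.29 for replicate 1 over 2, -1.11 for 1 over 3 and -2.46 for 2 over 3. Each of these medians lay outside 95% of 10000 random lists matched on expression, except that of antimicrobial genes over replicate 3. Stromal markers gave -7.61 for replicate 1 over 3 and -6.92 for 2 over 3, and -4.74 and -4.71 read-based. Many of them had counts near 0 in replicates 1 and 2, where the added 0.1 CPM sets the size of the ratio. TLR4 components stayed between 0.07 and 0.08 in all 3 pairs, inside the random range. Each pair is 1 library against another, so no p-value applies, and the libraries also differ in starting RNA.

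**Figure D4:**
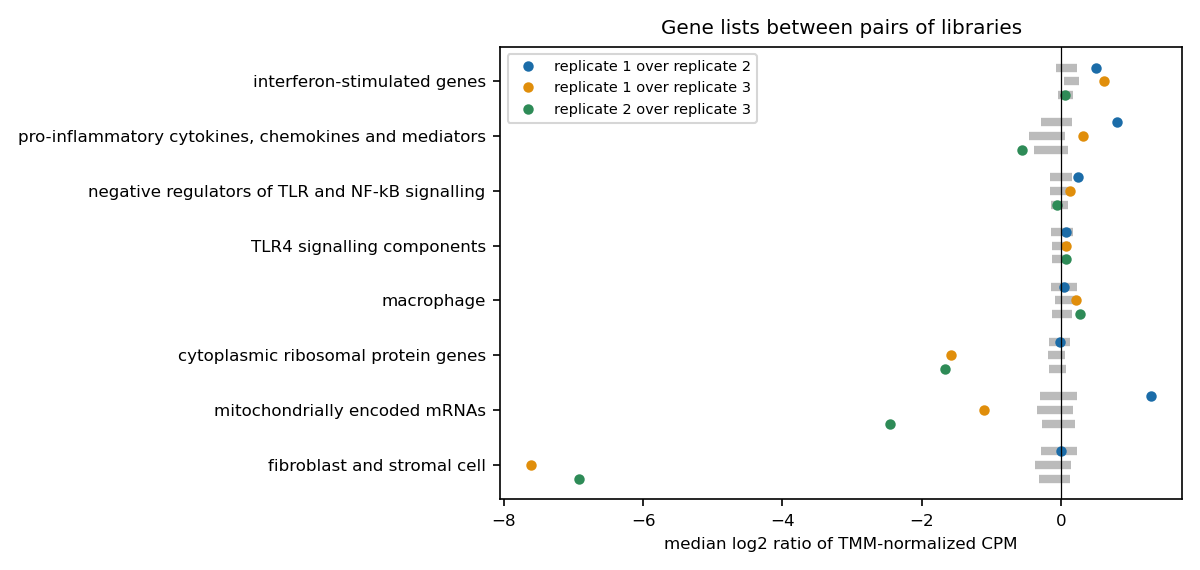
Median log2 ratio of TMM-normalized CPM between 2 libraries (horizontal axis) for 8 lists, 1 point per pair. Grey bars span 95% of random lists matched on mean expression; the ribosomal protein list lay at -1.58 and -1.67 in the pairs with replicate 3.

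Protein-coding transcripts held 15.4 ± 1.18% of TPM and 44.7 ± 3.00% of expected counts. Retained-intron isoforms, which keep an intron of their gene, held 12.48 ± 0.89% of TPM and 17.1 ± 1.23% of counts. Small nucleolar RNAs held 27.7 ± 5.21% of TPM but 0.31 ± 0.06% of counts, and small nuclear RNAs 14.7 ± 3.96% of TPM but 0.18 ± 0.12% of counts. In read-based TPM these classes held 6.87 ± 2.11% and 5.73 ± 2.90%. Genes overlapping ribosomal RNA repeats (Gm26917, Gm42418 and CT010467.1) took 9.37% of counts in replicate 1, 21.8% in replicate 2 and 14.4% in replicate 3. The 10 highest non-coding genes by TPM were Gm22988, Rmrp, Gm26917, Snord15b, Gm26447, Malat1, Rn7sk, Gm22513, Gm25835 and Gm25776. They were ranked by gene ID and not summed over IDs of 1 symbol. Gm22988 was at 77505 ± 23615 TPM and the higher of the Rmrp IDs at 69505 ± 27528 TPM. A small effective length raises TPM in this ranking. For Gm22988 it was 4.88, 2.52 and 2.94 in replicates 1, 2 and 3, from 5999, 2172 and 3386 expected counts. Malat1, ranked lower, held 10.3, 7.97 and 9.87% of the counts on genes. After Mx1, the highest protein-coding genes were the splicing-related Rsrp1 at 1602 ± 175 TPM, the inhibitory receptor gene Lilrb4a at 1349 ± 401 TPM, Tcirg1 at 1273 ± 309 TPM and Ikbke at 1161 ± 83.6 TPM. H2-K1, Fyb, Samhd1, Zeb2 and Hnrnpa2b1 followed, at 986 to 1101 TPM. Lilrb4a has a close paralog with which it can share reads, as do H2-K1 and other class I genes.

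**Figure D5:**
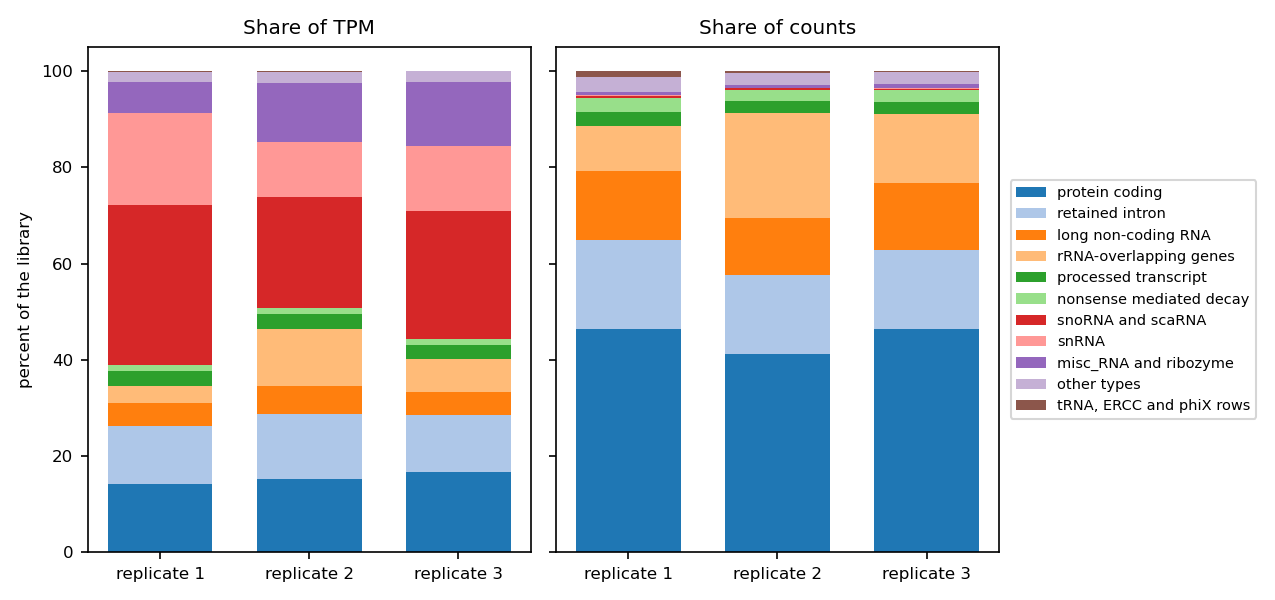
Percent of TPM (left) and of expected counts (right) in each transcript class, 1 stacked bar per library. Small nucleolar RNAs hold 27.7% of TPM and 0.31% of counts on average.

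Among 5480 protein-coding genes with at least 5 TPM, at least 2 expressed isoforms and an annotated retained-intron isoform, the median share of TPM in retained-intron isoforms was 48.6% (SD 2.83 over 3 libraries). In 2071 of them the share was over 50% in every library. The highest shares were in BC030499 and the amino acid transporter gene Slc1a5 (100% each), Lilrb4a (99.8 ± 0.11%), the fatty acid transporter gene Slc27a1 (99.0 ± 0.84%) and Rbm4b (98.9 ± 1.15%). Intronic reads can only be assigned where an annotated isoform keeps that intron, so these shares describe the annotation as well as the RNA.

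The read-based quantification gave higher levels than the alignment-based one for many genes. Of 15161 genes with at least 5 TPM in either, 4962 were over 2-fold higher in the read-based values in all 3 libraries and 91 were over 2-fold lower. Small non-coding genes were higher most often, 1322 of 1632, against 1562 of 9470 protein-coding genes. TPM has a fixed sum, of which small nucleolar RNAs held 27.7% alignment-based and 6.87% read-based. A larger share for these RNAs lowers the TPM of other genes. The median log2 ratio of read-based over alignment-based values was 0.46 for protein-coding genes. How much of the excess of higher genes comes from this scaling was not tested. The microRNA genes Gm24245, Gm23935 and Gm24270 were at 25143 ± 11782 TPM read-based and 0 alignment-based, and the pseudogenes Gm12895 and Gm12896 at 8448 ± 7122 TPM and 0. In the other direction the small nucleolar RNA copies Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 were at 420 ± 223 TPM alignment-based and 0.01 ± 0.01 TPM read-based, and Gm10925 at 86.8 ± 89.2 and 0.01 ± 0.01 TPM. Several of these genes hold identical values, so their reads are shared between copies.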

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

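The tRNA and phiX rows lie outside the gene measurement and hold reads above the limit that a count of 0 allows. The phiX row, a bacteriophage control sequence, took 156530 expected counts in replicate 1 (1.31%, Wilson 95% interval 1.30 to 1.32%), 82219 in replicate 2 (0.48%) and 46599 in replicate 3 (0.24%). The tRNA rows took 41, 29 and 44 counts in replicates 1, 2 and 3. In these alignment-based tables no count fell on the 96 ERCC spike-in rows; the read-based tables hold 11, 47 and 63 estimated counts there. No explanation was tested for these rows.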

How the results depend on the processing

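Of 576 values under alternatives, over 98 results, 499 kept their direction and side of the threshold, or stayed within the spread or count range set for them. Causes were not tested unless stated. With genes under a mean of 0.5 TPM left out, the immediate-early list (median 2.06) and the proliferation list (2.05) moved from above to below the background median and were called lower, dendritic markers were called lower (1.20), and TLR4 components lost their call (4.52); the background then holds only expressed genes. The same filter ended the call for negative regulators over cytokines (1.07) and for macrophage over osteoclast markers (4.47). It left 5 cell type lists with too few members for a value. In TMM-normalized CPM the mitochondrial list lost its call (3.94) and antimicrobial over cytokine genes gained one (2.81).

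The count of 24 over-dispersed genes became 677 with no filter, 180 at a mean of at least 50 reads, 1 in nuclear protein-coding genes only, and from 0 to 78 without 1 library (0 without replicate 2). The mean Pearson correlation was 0.952 at 50 reads, and 0.977, 0.976 and 0.984 without replicate 1, 2 and 3. The coefficient of variation was 0.383 with no filter and 0.299 at 50 reads. It was 0.221, 0.229 and 0.179 without replicate 1, 2 and 3, so it was lowest without replicate 3.

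Shares depended on the unit. In alignment-based expected counts they were 13.4% for long non-coding RNA, 0.65% for misc_RNA and ribozyme, 2.54% for nonsense-mediated decay, 2.66% for processed transcripts, 44.7% for protein-coding, 15.2% for rRNA-overlapping genes, 17.1% for retained introns, 0.18% for small nuclear and 0.31% for small nucleolar RNA. In read-based TPM the corresponding shares were 6.80, 4.57, 2.24, 7.64, 19.3, 9.65, 15.3, 5.73 and 6.87%.

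At 5 TPM 9953 genes were detected (660 long non-coding), at 0.1 TPM 3188 long non-coding genes, and read-based 23429 genes (4095 long non-coding). Genes higher in the read-based values numbered 7931 of 23728 at 1 TPM and 2241 of 7295 at 20 TPM; the share that differed either way stayed near the 33.3% found at 5 TPM, at 33.9% and 31.8%. Read-based ratios of ribosomal protein genes over replicate 3 were -1.11 and -1.15, and of cytokines -0.35 for replicate 2 over 3. Stromal ratios for 1 over 2, 1 over 3 and 2 over 3 were -0.35, -7.81 and -7.46 at 50 counts and -0.32, -4.74 and -4.71 read-based. No paired analysis was possible because the labels give 1 group. Depth limits stromal genes in replicates 1 and 2, many of which had under 3 counts.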

Other observations

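All tests here were chosen after the data were seen, except those of retained introns in genes read nearly only in replicate 3 and of GC content and length, whose outcomes were named before they were run. Splicing regulators were high on chromatin, with all 22 listed genes at 1 TPM or more in every library and a median log2(TPM + 1) of 7.71 (adjusted p = 0.00027 over 4 added lists, two-sided permutation test over genes). Srsf5 was at 626 ± 38.5 TPM, Rbm39 at 820 ± 21.1 TPM and Ddx5 at 907 ± 85.1 TPM (SD, n = 3). Their median share of TPM in retained-intron isoforms was 63.5% in 20 genes against 48.6% in 5480 (p = 0.012, permutation test over genes), and 57.8% in the read-based quantification, where it missed the threshold (p = 0.090). The list was chosen from the table of the highest genes, so its level is not independent evidence, and the genes named here were chosen after their values were seen.

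Class I antigen presentation genes had a median log2(TPM + 1) of 6.62 with all 11 present (adjusted p = 0.00027), including the activator gene Nlrc5 at 399 ± 63.5 TPM, the peptide transporter gene Tap1 at 111 ± 15.3 TPM and B2m at 99.2 ± 25.4 TPM. The 7 class II genes had a median of 2.83 (adjusted p = 0.35), with Cd74 at 14.8 ± 1.96 TPM and H2-Ab1 at 8.44 ± 2.09 TPM. Of 12 IRF and STAT genes, 9 were at 1 TPM or more in every library (list median 5.90, adjusted p = 0.00027). Irf2 was at 162 ± 14.5 TPM and Irf1 at 141 ± 11.6 TPM, and Irf4 and Stat4 were under 1 TPM in every library.

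Stromal, imprinted and, in the alignment-based counts only, Y-linked genes were high in replicate 3. There, 298 genes had at least 50 reads and no more than 5% of that in the other libraries together, against 2 genes for replicate 1 and 0 for replicate 2; they took 0.70% of its reads. Beside the stromal markers, all 8 imprinted genes (H19 at 0, 13 and 4430 counts) and all 14 matrix genes (Fn1 at 3, 4 and 5416 counts) of lists written after the data were seen were at least 10 times as high in replicate 3, and 1 of 4 Y-linked genes (Ddx3y). Depth is argued against by a median count ratio of 129 over replicate 2 on the stromal list, where total counts differ 1.13-fold; in the alignment-based counts, misread X-linked copies are argued against because 211 Y-linked reads would be due in replicates 1 and 2, where 1 was found, against 157 in replicate 3. The read-based tables hold 824, 1291 and 1588 Y-linked reads in replicates 1, 2 and 3, so there these reads are not confined to replicate 3. Total estimated counts in those tables rose in the same order, at 18600052, 31838203 and 33200218. Misread X-linked copies were not tested in the read-based tables. Xist stood at 13949, 12649 and 12606 CPM in replicates 1, 2 and 3. In the alignment-based counts replicate 3 thus held Y-linked reads beside an Xist level near that of the other libraries. Stromal cells as the source of these transcripts stay open, since the 10 of 11 markers at least 10 times as high are the pattern itself. Macrophage markers were higher in replicate 2 than in replicate 3 by a median of 0.28 (12 of 15 genes). Replicate 1 over 3 gave 0.21 (11 of 15 genes), inside the random range. For 21 genes with at least 1000 reads in replicate 3, replicate 2 held a median of 0.25% of those reads and replicate 1 a median of 0%. Replicate 2 had reads for all 21 genes and replicate 1 for 10. These counts show that transcripts of stromal genes were present in replicate 3. They do not decide which cells made them or how they entered the library. The RNA may have entered as mature RNA: retained-intron isoforms held a median of 0.14% of TPM in 134 such genes, against 30.9 to 42.5% in 95% of matched random lists. No biological explanation was tested, since the design gives 1 group.

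Interferon-stimulated genes were higher in replicate 1 than in the other libraries for all 25 genes tested. Removing the trend over GC content and effective length left medians of 0.47 over replicate 2 and 0.52 over replicate 3, outside the random ranges, from 0.51 and 0.61 before. The list lay at least 0.53 above the median of all genes under TMM and relative log expression, but a scaling factor moves every gene alike, so this does not test scaling. The starting amount was given by 1 library each and was not tested; no biological explanation was tested.

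For Gm26447 and Snord22, small nucleolar RNAs, TPM was 0 in libraries that hold their reads. Gm26447 had 48803, 0 and 48684 TPM from 1063, 763 and 946 expected counts, and Snord22 had 21965, 0 and 0 TPM from 372, 665 and 684 counts. They are the 2 small RNA genes with a TPM of 0 in a library and at least 1000 in another, picked without regard to reads but after both were known. Loss of the RNA is argued against by a median ratio of 0.91 in CPM between those libraries and the others. An effective length near 0 is a candidate explanation: reads and an effective length of 0 were found in all 3 library values with a TPM of 0. Transcripts with an effective length under 50 held 43.5 ± 6.41% of TPM and 0.41 ± 0.16% of counts. No biological explanation was tested.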
